A study of Drosophila melanogaster with 8 samples.

How the data were processed

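RNA of the larval fat body of Drosophila melanogaster was measured by RNA sequencing in 8 samples that form 4 groups of 2: fed wild type, wild type starved for 4 h, wild type starved for 16 h, and homozygous CPSF5 mutant larvae starved for 16 h. Groups were taken from the genotype and starvation labels of each sample. The labels carry no replicate numbers, so replicates were numbered in accession order. The labels do not say that the 2 samples of a group came from separate animals or cultures, so every p-value measures only the spread between these samples, which may be technical.

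Per the labels' protocols, RNA was extracted with Trizol, its quality was assessed on a Bioanalyzer, and libraries were made with a stranded total RNA kit that removes ribosomal RNA (Ribo-Zero Gold). Per the submitters' processing notes, STAR 2.5.3 and the fly genome build BDGP6 were used. The tool that turned reads into expression values, its version, the annotation release, any trimming and whether strand was used in counting are not given in the sources used here. The authors deposited TPM values (a length-adjusted share of transcripts, scaled so that all libraries sum to nearly the same total over all RNA classes) in a table of 17471 genes and a table of 34485 transcripts, with 1 column per sample and no pooling. Gene values equalled the sum of their isoforms, within a relative tolerance of 0.0001, for 17068 of 17119 genes (99.7%) that could be compared. TPM keeps no read depth, so the depth of each library is unknown, no counting interval was computed, and the precision of low values rests on the spread between replicates alone. Because TPM is a share of all RNA, a large share of ribosomal or 7SL RNA in a library lowers the value of every other gene in it.

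Genes were named with a later BDGP6 annotation, from which the coordinates were also taken. Of the gene identifiers, 17249 matched it directly, 131 were matched because their values equalled the summed isoforms of 1 current gene, and 91 stayed unmatched and kept their identifier. Of the transcripts, 34114 matched and 371 did not, and the unmatched ones were left out of the isoform tests.

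Each library's TPM was divided by a median-of-ratios factor, computed over genes at 1 or more in all 8 libraries. Values called scaled TPM are TPM after this division. Genes with a mean of 1 or more scaled TPM over the 8 libraries were tested (8332 genes) with limma 3.58.1 in R 4.3.3, on log2(scaled TPM + 1), with 1 mean per group over all 8 libraries, moderated variances with a trend on expression level, two-sided tests, and Benjamini-Hochberg adjustment over all genes of a comparison. This leaves 4 residual degrees of freedom, to which moderation added a median of 2.16. A gene passed at an adjusted p under 0.05. All log2 fold changes are on the log2(scaled TPM + 1) scale, which understates the change of genes at low levels, and each SE is the standard error from limma. Means are given as mean ± SD of scaled TPM over the 2 libraries of a group. With 2 libraries against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333, so calls rest on the spread pooled by limma.

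Isoform use was tested with limma on log2((isoform TPM + 1)/(TPM of the gene's other isoforms + 1)), for isoforms with a mean share of 5% to 95% in genes with a mean of 5 or more TPM and at least 2 isoforms (5141 isoforms of 1948 genes), with the same design. The shares are estimates by the authors' tool from short reads.

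In all, 39 gene lists (pathways, complexes and markers of the fat body and of other larval tissues) were written before the data were examined, as were the groups, tests, filters, alternative settings and the rule for naming genes. Of these, 35 had the minimum of 3 tested members and were tested with camera in limma (preset inter-gene correlation of 0.01, two-sided, Benjamini-Hochberg over the lists of a comparison), and 5 members or name patterns found no gene. Counts of members past the gene test are given over all genes tested and, where said, adjusted over the list alone. With an estimated correlation, no list passed in any of the 3 main comparisons (camera in limma; at an unadjusted p under 0.05, 2, 2 and 5 lists for 4 h against fed, 16 h against fed and mutant against wild type), and the lowest adjusted p was 0.514, 0.42 and 0.233.

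The genes named are Cpsf5, Atg1 and Atg8a; the 10 largest rises and 10 largest falls of each main comparison among genes past the test whose groups did not overlap and whose higher group averaged 5 or more scaled TPM, leaving out noncoding classes and pseudogenes; and, for each list described, up to 4 members with the largest change among those past the test, or, where none passed, up to 2 with the smallest p. Named isoforms are the 5 largest rises and 5 largest falls in share past the test with ranges that did not overlap, plus those of autophagy and cleavage and polyadenylation genes that passed. A few further genes were named after their values were seen, and are said to be so.

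The comparisons were 4 h starved against fed, 16 h starved against fed, and 16 h against 4 h starved, all in wild type, and mutant against wild type, both starved for 16 h. The mutant was also set against fed wild type; as a fed mutant was not analysed here, that comparison mixes genotype with starvation. Overlaps of calls are given beside the number expected for independent lists and beside 100 simulations of unchanged groups, 20 of them with calls counted. The gene, isoform and list tests were tested on simulated data with known answers. Of 100 genes changed 2-fold and 100 changed 4-fold among 7974 simulated genes, the 4 h comparison found 29 and 80 with 9 false calls, the 16 h comparison 31 and 84 with 12, and the mutant comparison 29 and 82 with 5. Of 100 isoforms changed 4-fold and 100 changed 16-fold among 5141, the same comparisons found 72 and 95, 76 and 97, and 72 and 94, with 3, 9 and 7 false calls. Of 35 lists, the 1 changed list was found in each comparison, with 2, 0 and 0 false calls.

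The alternatives tried were TPM as deposited, TPM rescaled over genes outside the noncoding and mitochondrial classes, quantile normalization, pseudocounts of 0.1 and 5, no filter and a mean of 5 or more, no trend, only the 2 groups compared, a change of at least 2-fold, other settings for isoforms, an estimated correlation for lists, and leaving out each library in turn, where the lone sample of its group is assumed to vary like the other groups. Leaving out wild-type 16 h replicate 1 and mutant replicate 2 together, and a block on accession order, were added after seeing the data. Groups of 2 allow no test of other sample splits or of outlying samples. Figures used matplotlib 3.10.9, and tables pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.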

Results

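The larval fat body is the fly's main store of fat, glycogen and protein and its main site of nutrient sensing. Its RNA was sequenced in wild-type larvae (Oregon R, a standard laboratory strain) that were fed, starved for 4 h or starved for 16 h, and in larvae homozygous for the CPSF5 allele H11 that were starved for 16 h, with 2 libraries in each group. Cpsf5 encodes a subunit of cleavage factor I, which binds pre-mRNA near polyadenylation sites and takes part in the choice between them. No fed mutant was analysed here, so the mutant is set against wild type starved as long. Each mean ± SD below is over n = 2 libraries, in scaled TPM unless a share is named, and log2 fold changes (log2FC) carry the SE and adjusted p of limma. TPM keep no read depth, so the depth is unknown.

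The libraries differed in what RNA they held. The 7SL RNA of the signal recognition particle took between 11.8% (wild-type 16 h replicate 1) and 40.3% (4 h replicate 2) of all TPM. Nuclear ribosomal RNA took 5.19% and 6.79% in the fed libraries, 12.6% and 14% at 4 h, 48.8% and 31.1% in wild type at 16 h, and 4.58% and 5.41% in the mutant. Nuclear protein-coding genes held 41.6% and 39.8% of TPM in fed libraries but 17.6% and 28.1% in wild type at 16 h. The share of ribosomal RNA therefore moved with the group, and wild-type 16 h replicate 1 stood highest. Median-of-ratios factors ran from 0.537 in that library to 1.52 in fed replicate 1. Without this scaling the median log2FC of all genes was -0.526 at 4 h, -0.820 at 16 h and 0.767 in the mutant, and with rescaling over coding genes it was -0.332, -0.317 and 0.437, so changes are given relative to the median gene. Values and counts given for those scalings carry this common shift. The first principal component (51% of the variance) held fed libraries at -67.0 and -66.8, mutant libraries at -47.2 and -48.2, and the 4 starved wild-type libraries between 51.7 and 68.1. The second (29.2%) set fed and mutant libraries farthest apart, at 54.12 and 58.25 against -60.19 and -72.65, with the starved wild-type libraries between 2.2 and 8.99. Spearman correlations across genes between the 2 replicates of a group were 0.958 for fed, 0.902 for 4 h, 0.886 for 16 h and 0.938 for the mutant, and 4 h replicate 2 and 16 h replicate 2 correlated at 0.908.

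**Figure D1:**
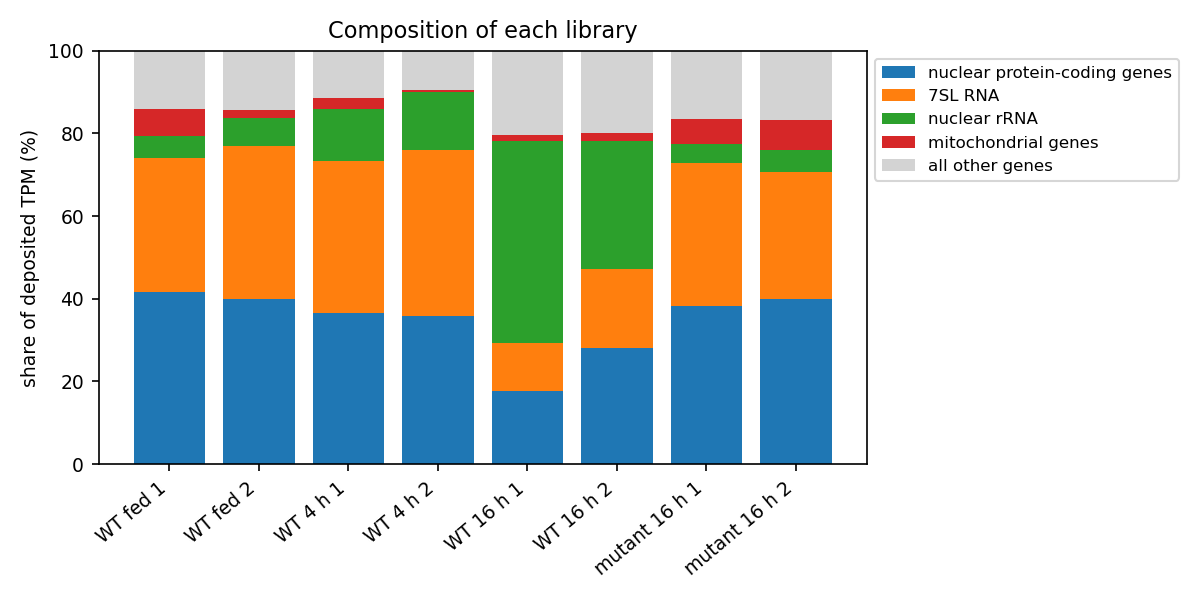
Share of the deposited TPM (percent, y axis) held by nuclear protein-coding genes, 7SL RNA, nuclear ribosomal RNA, mitochondrial genes and all other genes in each of the 8 libraries (x axis). Nuclear ribosomal RNA reached 48.8% and 31.1% in wild type starved for 16 h, against 5.19% and 6.79% in fed wild type.

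The mutated gene itself, Cpsf5 (FBgn0035987; chromosome 3L, 9411038 to 9413835, plus strand), stood at 12.0 and 10.9 scaled TPM in the fed libraries, 6.47 and 3.62 at 4 h, 5.06 and 4.20 at 16 h, and 3.60 and 3.01 in the mutant. It fell in wild type at 4 h (log2FC -1.08, SE 0.24, adjusted p = 0.0118) and at 16 h (-1.15, SE 0.24, adjusted p = 0.00929). The mutant did not differ from wild type at 16 h (-0.39, SE 0.24, adjusted p = 0.256; 0.33 without scaling, also not passed), and the labels do not say what the allele changes, so the RNA level neither checks nor contradicts the genotype label. The 4 h call was lost without fed replicate 1 (adjusted p = 0.0662), and the 16 h call without fed replicate 1 (0.0552) or 16 h replicate 2 (0.0504). The isoform Cpsf5-RB (9411038 to 9413637), whose annotated 3' UTR of 1375 nt is longer than the 423 nt of Cpsf5-RC, made up 8.19% ± 1.01 of the gene's TPM in fed larvae, 37.7% ± 0.06 at 4 h, 50.3% ± 5.8 at 16 h and 15.4% ± 0.99 in the mutant. In unscaled TPM, Cpsf5-RB stood at 1.32 in fed larvae, 1.79 at 4 h, 1.5 at 16 h and 0.61 in the mutant, near the pseudocount of 1. Cpsf5-RC stood at 14.95, 2.96, 1.46 and 3.37. The share of Cpsf5-RB thus rose in starved wild type mainly as Cpsf5-RC fell. That share rose at 4 h (log2 ratio change 2.29, adjusted p = 0.00406) and 16 h (2.79, adjusted p = 0.00232), and was lower in the mutant than in wild type at 16 h (-1.45, adjusted p = 0.0127). The mutant call was lost without 16 h replicate 2 (0.0708), mutant replicate 1 (0.0812) or mutant replicate 2 (0.0655).

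Atg1 (FBgn0260945; chromosome 3L, 12784429 to 12805116, minus strand), the kinase that starts autophagy, rose from 2.03 ± 0.00887 in fed larvae to 8.47 ± 1.98 at 4 h (log2FC 1.63, SE 0.23, adjusted p = 0.00205) and 6.37 ± 1.69 at 16 h (1.27, SE 0.23, adjusted p = 0.00544). It was lower in the mutant, at 3.02 ± 0.7 (-0.87, SE 0.23, adjusted p = 0.0333 against wild type at 16 h). That last call was not passed without scaling (-0.14, adjusted p = 0.698) or with rescaling over coding genes (-0.63, adjusted p = 0.143), where the median gene stood at 0.767 and 0.437, so its place relative to the median gene moved little. It was lost without fed replicate 1 (0.0658), fed replicate 2 (0.0661), 16 h replicate 2 (0.136), mutant replicate 1 (0.157) or mutant replicate 2 (0.0636), and the 16 h rise was not passed without scaling (0.39, adjusted p = 0.308; median gene at -0.820). Atg8a (FBgn0052672; chromosome X, 10764878 to 10768338, minus strand), which coats autophagosome membranes, rose from 27.4 ± 0.017 to 188 ± 36.7 at 4 h (2.72, SE 0.23, adjusted p = 0.000283) and 161 ± 14.3 at 16 h (2.51, SE 0.23, adjusted p = 0.000392). In the mutant it stood at 145 ± 20.9, above fed (2.36, SE 0.23, adjusted p = 0.000665) and not different from wild type at 16 h (-0.15, SE 0.23, adjusted p = 0.647). The isoform Atg8a-RA made up 96.8% ± 2.12 of the gene in fed larvae, 97.1% ± 1.78 at 4 h, 91.8% ± 0.721 at 16 h and 93.1% ± 0.144 in the mutant, and its share did not pass in any of these comparisons. Atg1-RA made up 52.9% ± 23.3, 77.8% ± 28.1, 90% ± 14.1 and 79.9% ± 14.6 of its gene, whose level was under the filter of the isoform test.

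**Figure D2:**
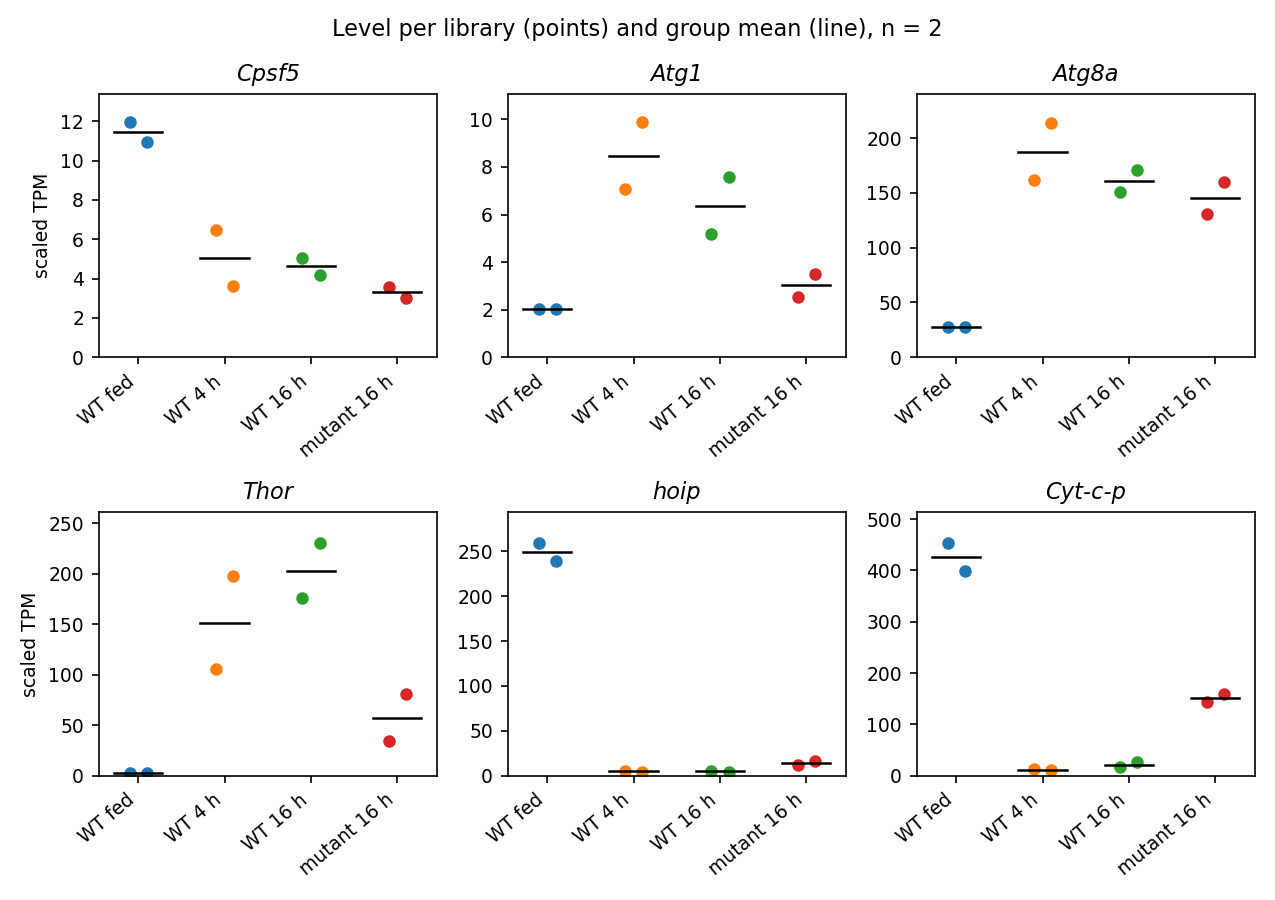
Scaled TPM (y axis, linear) of 6 genes in the 4 groups (x axis), where points are libraries and lines are means of n = 2. Atg8a stood at 27.4 in both fed libraries and between 131 and 214 in all 6 starved ones, while hoip stood at 249 ± 14.1 in fed larvae and at 14.2 ± 2.53 or less in each starved group.

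Many autophagy and insulin-pathway genes rose after 4 h of starvation in wild type. Atg7, an enzyme of Atg8 conjugation, went from 0.55 ± 0.00267 to 16.0 ± 5.43 (log2FC 3.41, SE 0.27, adjusted p = 0.00022), and Atg18b rose (3.68, SE 0.30, adjusted p = 0.000261). Thor, the 4E-BP repressor of translation and a target of FOXO, went from 2.82 ± 0.507 to 151 ± 64.9 (5.25, SE 0.48, adjusted p = 0.000378), and the insulin-like peptide Ilp6 rose (5.14, SE 0.39, adjusted p = 0.000211). Of 29 autophagy genes tested, 20 rose and 2 fell (camera adjusted p = 4.23e-06, or adjusted p = 0.514 with an estimated correlation), against 13 and 2 without scaling. Of 16 genes of insulin signalling and FOXO targets, 8 rose and 1 fell (camera adjusted p = 0.0147, or adjusted p = 0.531 with an estimated correlation), against 3 and 2 without scaling. Without fed replicate 2, 5 of these rose, and without 4 h replicate 1, 3 fell. Both pairs of counts were the same adjusted over the list alone.

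Genes that build ribosomes and charge transfer RNA fell. hoip, a protein of small nucleolar RNPs, dropped from 249 ± 14.1 to 4.87 ± 0.916 (log2FC -5.42, SE 0.20, adjusted p = 3.93e-05), and nop5 (-5.02, SE 0.22, adjusted p = 3.93e-05), fibrillarin (Fib; -4.87, SE 0.25, adjusted p = 5.36e-05) and Nop60B (-4.78, SE 0.24, adjusted p = 5.03e-05) fell likewise. Of 29 ribosome biogenesis genes, 28 fell and 1 rose, with a median log2FC of -3.86 (camera adjusted p = 9.22e-15, or adjusted p = 0.514 with an estimated correlation). All 17 aminoacyl-tRNA synthetases fell, among them LeuRS (-3.06, SE 0.23, adjusted p = 0.000181) and IleRS (-2.92, SE 0.22, adjusted p = 0.000192), with a median of -2.12 (camera adjusted p = 4.37e-08, or adjusted p = 0.514 with an estimated correlation). Both counts were the same adjusted over the list alone. Of 88 ribosomal protein genes 6 fell and none rose (limma; 3 fell adjusted over the list alone), but 13 fell without scaling, 11 under quantile normalization and 40 of 92 with rescaling over coding genes. The list was not called (camera adjusted p = 0.384). The largest falls were in the divergent paralogues RpLP0-like (-4.25, SE 0.14, adjusted p = 3.93e-05) and RpL7-like (-2.39, SE 0.20, adjusted p = 0.000261). Leaving out any 1 fed, 16 h or mutant library left 3 of them called.

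Many oxidative phosphorylation and glycolysis genes fell. Muscle markers fell with them (10 of 11), and whether less muscle tissue adds to these falls was not tested. Cytochrome c (Cyt-c-p) dropped from 426 ± 39.4 to 12.2 ± 0.441 (log2FC -5.02, SE 0.23, adjusted p = 4.22e-05), and ATPsynbeta (-2.27, SE 0.38, adjusted p = 0.00362) and ND-ACP (-2.22, SE 0.20, adjusted p = 0.000353) fell too. Of 72 nuclear-encoded oxidative phosphorylation genes 63 fell and none rose (64 adjusted over the list alone, camera adjusted p = 1.08e-10, or adjusted p = 0.645 with an estimated correlation). Hexokinase C (Hex-C) fell (-4.93, SE 0.41, adjusted p = 0.000282), while the pyruvate dehydrogenase kinase Pdk rose (2.37, SE 0.37, adjusted p = 0.00294). 10 of 14 glycolysis genes fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.0163, or adjusted p = 0.514 with an estimated correlation). The other metabolic lists went both ways and were not called. Of 24 lipolysis and fatty acid oxidation genes, 5 rose, led by the carnitine palmitoyltransferase whd (2.52, SE 0.38, adjusted p = 0.00245). Another 5 fell, led by CG3902 (-2.84, SE 0.19, adjusted p = 0.000132). The list's median of 0.16 turned to -0.36 without scaling, where 3 rose, and -0.31 with rescaling over coding genes, and 8 rose under quantile normalization (camera adjusted p = 0.596). Of 19 fatty acid and triglyceride synthesis genes, 8 fell and 2 rose (camera adjusted p = 0.173), and Baldspot fell (-3.29, adjusted p = 0.000452). Of 14 genes of gluconeogenesis, trehalose and glycogen, 7 fell and 4 rose (camera adjusted p = 0.489; 9 and 2 without scaling, 4 and 4 under quantile normalization), the latter including Pepck2 (3.35, adjusted p = 0.00129) and the trehalose transporter Tret1-1 (3.07, adjusted p = 0.000644). These counts were the same adjusted over the list alone. Single libraries moved them. Without fed replicate 2, 3 lipolysis genes rose. Without fed replicate 1, 5 synthesis genes fell, and 3 gluconeogenesis genes fell without either fed library and 4 without 4 h replicate 2.

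Genes of late larval life were among the largest rises at 4 h. The fat body gene Fbp1, a receptor for storage proteins, went from 9.78 ± 4.55 to 16209 ± 10380.0 (log2FC 10.46, SE 0.57, adjusted p = 6.23e-05). The salivary glue genes Sgs7 (17.5 ± 20.2 to 14614 ± 942; 10.28, SE 1, adjusted p = 0.000477), Sgs8 (10.10, SE 0.67, adjusted p = 0.000124), Sgs5 (10.06, SE 0.89, adjusted p = 0.000332) and Sgs5bis (9.30, SE 0.45, adjusted p = 4.51e-05) rose with the uncharacterised genes CG15404 (10.70, adjusted p = 7.09e-05), CG31698 (10.64, adjusted p = 5.79e-05) and CG7606 (10.21, adjusted p = 6.46e-05). Sgs5 and Sgs5bis are paralogues, so their split of reads is uncertain. Of 10 salivary gland markers, 7 rose, including Eig71Ee (8.45, adjusted p = 7.42e-05, camera adjusted p = 0.00657, or adjusted p = 0.514 with an estimated correlation). Of 13 ecdysone-response genes, 10 rose and none fell (camera adjusted p = 2.74e-05, or adjusted p = 0.514 with an estimated correlation). They included the transcription factors br, from 0.967 ± 0.0735 to 14.6 ± 3.57 (2.97, SE 0.18, adjusted p = 8.2e-05), and Eip74EF (2.53, SE 0.12, adjusted p = 4.51e-05), as well as MsrA (4.57, adjusted p = 0.00153). Of 6 larval storage proteins, 3 rose (camera adjusted p = 0.173): Fbp1, Fbp2 (3.61, adjusted p = 0.0152) and Lsp2, from 4038 ± 2355 to 16596 ± 4315 (2.15, adjusted p = 0.0133). Lsp2 was not called under quantile normalization (0.92, adjusted p = 0.223). Without fed replicate 1 the p was 0.0603 for Lsp2 and 0.0557 for Fbp2, and without 4 h replicate 2 it was 0.0664 and 0.0791, so that 1 storage gene stayed called in either case. Of 10 fat body markers, which include Fbp1, Fbp2 and Lsp2, 7 rose (camera adjusted p = 0.0205, or adjusted p = 0.637 with an estimated correlation), 4 of them without scaling, where 1 fell, 2 without fed replicate 1 and 3 without 4 h replicate 2. These counts were the same adjusted over the list alone.

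Some immune, stress and signal genes also changed by large amounts. Drosomycin (Drs), an antifungal peptide, went from 1.46 ± 0.893 to 2930.1 ± 2307 (log2FC 10, SE 0.74, adjusted p = 0.000184) and BomS3 rose (6.80, SE 0.91, adjusted p = 0.00163). Drosocin (Dro) fell (-6.19, SE 0.94, adjusted p = 0.00265), as did diptericin B (DptB; -5.49, SE 1.24, adjusted p = 0.0124). DptB was not called without fed replicate 2 (adjusted p = 0.0736) or 4 h replicate 1 (0.0577). Of 31 immune genes, 11 rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.214), a balance that turned to 8 against 11 without scaling and 9 against 11 with rescaling over coding genes. 3 fell without fed replicate 2 and 3 without 4 h replicate 1. The small heat shock genes Hsp23 (3.08 ± 1.64 to 2638 ± 537; 9.39, SE 0.88, adjusted p = 0.000419) and Hsp27 (5.85, SE 0.84, adjusted p = 0.00206) rose, and the mitochondrial chaperone Hsp60A fell (-4.05, SE 0.28, adjusted p = 0.000151). These were among 2 rises and 3 falls in 20 heat shock genes (the same adjusted over the list alone, camera adjusted p = 0.509), and 1 fell without fed replicate 2. Of 12 fat body-derived signals, 6 rose, including the growth-blocking peptide Gbp1 (4.63, adjusted p = 0.000161), and 3 fell, including the adenosine deaminase Adgf-A (-2.01, adjusted p = 0.0016; the same adjusted over the list alone, camera adjusted p = 0.173), a balance that turned to 3 against 4 without scaling or with rescaling over coding genes. Without fed replicate 2, 2 rose.

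Many cell cycle and muscle genes fell, with smaller numbers of cleavage and polyadenylation and midgut genes. Of 24 DNA replication and cell cycle genes, 18 fell, led by PCNA (-2.56, adjusted p = 0.000561), geminin (-2.31, adjusted p = 0.000249) and Cdc45 (-2.31, adjusted p = 0.000124), and 1 rose (camera adjusted p = 0.000103, or adjusted p = 0.645 with an estimated correlation). Of 18 cleavage and polyadenylation factors, 9 fell and none rose (camera adjusted p = 0.0759, not passed), led by Cpsf6, the partner of Cpsf5 in cleavage factor I (14.9 ± 0.112 to 4.99 ± 0.554; -1.41, SE 0.14, adjusted p = 0.000586), CstF50 (-1.35, adjusted p = 0.0046) and Cpsf160 (-1.19, adjusted p = 0.00302). Without fed replicate 2, 5 fell. Of 11 muscle markers, 10 fell, among them Act57B (-3.54, adjusted p = 0.00525) and Mhc (-2.69, adjusted p = 0.00488, camera adjusted p = 0.00657, or adjusted p = 0.645 with an estimated correlation). Of 12 midgut markers, 5 fell (camera adjusted p = 0.116), including the proteases Jon65Aiv (-6.04, adjusted p = 0.00332) and deltaTry (-5.64, adjusted p = 0.00223). The counts of these lists were the same adjusted over the list alone. Other large falls were in the glutathione transferase GstD7 (-6.48, adjusted p = 0.000115), the glycerophosphate oxidase Gpo1 (-6.09, adjusted p = 4.51e-05), CG14302 (-5.66, adjusted p = 0.00228), CG32073 (-5.43, adjusted p = 0.00337) and the abundant Nplp2 (-5.47, adjusted p = 0.0362), which stood at 1582 and 27.8 in the 4 h libraries. Nplp2 was not called without any 1 fed, 16 h or mutant library (adjusted p from 0.0539 without 16 h replicate 1 to 0.133 without fed replicate 1).

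In all, 3979 of 8332 genes passed at 4 h (47.8%), 1759 higher and 2220 lower, 2727 of them by at least 2-fold and 256 of them noncoding or mitochondrial. The share of higher calls was 44.2%, against 20.9% without scaling, 25.2% with rescaling over coding genes and 48.4% under quantile normalization.

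After 16 h many autophagy and insulin-pathway genes stood above fed, and most ribosome biogenesis genes below. Atg7 was at 14.8 ± 3.88 (log2FC 3.33, SE 0.27, adjusted p = 0.00025) and Thor at 203 ± 38.5 (5.73, SE 0.48, adjusted p = 0.000295). Atg18b (3.46, adjusted p = 0.000334) and Ilp6 (5.51, adjusted p = 0.000173) were higher too. Of 29 autophagy genes, 19 rose and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 9.75e-06, or adjusted p = 0.43 with an estimated correlation), and without scaling 4 rose and 2 fell. Of 16 insulin and FOXO genes, 11 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.000492, or adjusted p = 0.42 with an estimated correlation), against 4 and 2 without scaling. hoip was at 5.13 ± 0.694 (-5.35, SE 0.20, adjusted p = 5.97e-05), and Fib fell as well (-4.59, adjusted p = 7.49e-05). Of 29 ribosome biogenesis genes 27 fell (camera adjusted p = 6.38e-14, or adjusted p = 0.42 with an estimated correlation). All 17 synthetases fell, among them HisRS (-2.78, adjusted p = 0.000291; camera adjusted p = 7.04e-08, or adjusted p = 0.42 with an estimated correlation). Both counts were the same adjusted over the list alone. Of 88 ribosomal protein genes, 12 fell (4 adjusted over the list alone, camera adjusted p = 0.00463, or adjusted p = 0.732 with an estimated correlation), with RpLP0-like (-3.80, adjusted p = 5.97e-05). That count was 85 without scaling, 65 with rescaling over coding genes and 41 under quantile normalization. It was 4 without 16 h replicate 1, the library richest in ribosomal RNA, 5 without 16 h replicate 2 or fed replicate 2, 6 without fed replicate 1, 27 without 4 h replicate 1 and 25 without 4 h replicate 2.

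At 16 h many oxidative phosphorylation and glycolysis genes again fell along with muscle markers (9 of 11). Cyt-c-p was at 21.9 ± 5.67 (log2FC -4.24, SE 0.23, adjusted p = 7.45e-05), and Cyt-c1 (-2.90, adjusted p = 0.000189) and UQCR-C2 (-2.63, adjusted p = 0.000361) fell with it. 63 of 72 oxidative phosphorylation genes fell and none rose (64 adjusted over the list alone, camera adjusted p = 3.43e-13, or adjusted p = 0.555 with an estimated correlation). Of 14 glycolysis genes, 11 fell, including Hex-C (-5.48, adjusted p = 0.000202), Tpi (-2.21, adjusted p = 0.000969) and Eno (-2.06, adjusted p = 0.000699), and Pdk rose (2.43, adjusted p = 0.00263, the same adjusted over the list alone, camera adjusted p = 0.00326, or adjusted p = 0.42 with an estimated correlation). Of 24 lipolysis and oxidation genes, 12 fell and 4 rose (the same adjusted over the list alone, camera adjusted p = 0.147; 16 and 2 without scaling, 7 and 4 under quantile normalization), with the lipase brummer (bmm; 2.90, adjusted p = 0.00363) and whd (2.75, adjusted p = 0.00171) up and CG3902 (-3.40, adjusted p = 8.04e-05) and Hmgs (-2.27, adjusted p = 0.000161) down. 6 fell without fed replicate 2, 7 without 16 h replicate 2, and 2 rose without fed replicate 1 or 16 h replicate 1. Of 19 fatty acid and triglyceride synthesis genes, 7 fell and 2 rose (the same adjusted over the list alone, camera adjusted p = 0.25), with malic enzyme (Men; -3.28, adjusted p = 0.000355) and Gpdh1 (-2.32, adjusted p = 0.00104) down and a list median of -0.24 that turned to 0.05 under quantile normalization. Of 14 gluconeogenesis, trehalose and glycogen genes, 7 fell and 3 rose (the same adjusted over the list alone, camera adjusted p = 0.469), led by the transcription factor sug (3.55, adjusted p = 0.000192). 4 fell without fed replicate 1, fed replicate 2 or 16 h replicate 1.

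Fbp1 (7369 ± 2445; log2FC 9.44, SE 0.57, adjusted p = 9.8e-05), Sgs7 (18165 ± 13640.0; 10.36, SE 1, adjusted p = 0.000463), Sgs5 (10.04, adjusted p = 0.000347), Sgs8 (8.74, adjusted p = 0.00021), Sgs5bis (8.66, adjusted p = 6.85e-05), Eig71Ee (9.11, adjusted p = 7.13e-05), CG15404 (9.42, adjusted p = 0.000123), CG31698 (9.32, adjusted p = 9.7e-05) and CG7606 (8.93, adjusted p = 0.000113) were again among the largest rises. Of 10 salivary gland markers, 7 rose (camera adjusted p = 0.000525, or adjusted p = 0.42 with an estimated correlation). Of 13 ecdysone-response genes, 10 rose and 1 fell (camera adjusted p = 0.000492, or adjusted p = 0.42 with an estimated correlation), including br (18.0 ± 1.13; 3.27, SE 0.18, adjusted p = 7.21e-05), Eip74EF (2.87, adjusted p = 5.97e-05) and the receptor EcR (2.74, adjusted p = 0.000458). Lsp2 stood at 24216 ± 691 (2.72, SE 0.50, adjusted p = 0.00525; 0.75, adjusted p = 0.307 under quantile normalization), and 3 of 6 storage genes rose (camera adjusted p = 0.0962), whereas under quantile normalization 1 rose and 2 fell and the median turned from 1.81 to -0.31. Of 10 fat body markers 7 rose (camera adjusted p = 0.00767, or adjusted p = 0.529 with an estimated correlation), and 4 rose under each other scaling and without fed replicate 1, 16 h replicate 1 or 16 h replicate 2. These counts were the same adjusted over the list alone.

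Drs was at 389 ± 110.3 (log2FC 7.33, SE 0.74, adjusted p = 0.00056) and the stress peptide TotA at 772 ± 154 (3.96, SE 0.23, adjusted p = 9.4e-05). Of 31 immune genes, 10 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.25), with a median of -0.02 but a mean of 0.56 and an upward test, while 5 rose and 10 fell without scaling and 8 and 7 with rescaling over coding genes. Rises numbered 3 without fed replicate 1, 4 without fed replicate 2 and 6 without 16 h replicate 1, and falls 1, 2 and 2. Hsp23 (8.06, adjusted p = 0.000734) and Hsp27 (5.28, adjusted p = 0.00305) were among 4 rises and 2 falls in 20 heat shock genes (3 and 2 adjusted over the list alone, camera adjusted p = 0.0856), against 3 and 4 without scaling. 10 rose without 16 h replicate 1 and 2 without fed replicate 2. Gbp1 rose (4.65, adjusted p = 0.000168), and the peptide gene sun fell (-2.21, adjusted p = 0.00261), among 7 rises and 3 falls in 12 fat body signals (the same adjusted over the list alone, camera adjusted p = 0.099), but without scaling 3 rose and 3 fell, with a median of -0.19 in place of 0.93, and with rescaling over coding genes 4 and 3. Without fed replicate 2, 4 rose.

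At 16 h, 17 of 24 cell cycle genes fell, including PCNA (log2FC -2.94, adjusted p = 0.000342) and Mcm3 (-2.66, adjusted p = 0.000405, 18 fell and 1 rose adjusted over the list alone, camera adjusted p = 5.91e-05, or adjusted p = 0.555 with an estimated correlation). Of 18 cleavage and polyadenylation factors, 11 fell and 2 rose (the same adjusted over the list alone, camera adjusted p = 0.0145, or adjusted p = 0.529 with an estimated correlation), with Cpsf6 at 3.50 ± 0.601 (-1.83, SE 0.14, adjusted p = 0.000242) and CstF50 (-1.69, adjusted p = 0.00188). 6 fell without fed replicate 1 and 7 without fed replicate 2. Of 11 muscle markers, 9 fell (the same adjusted over the list alone, camera adjusted p = 0.0131, or adjusted p = 0.619 with an estimated correlation), with Mhc (-2.36, adjusted p = 0.00801). 1 fell without fed replicate 1, 5 without fed replicate 2, 2 without 16 h replicate 1 and 5 without 16 h replicate 2. Of 12 midgut markers 5 fell, led by deltaTry (-5.14, adjusted p = 0.00316; the same adjusted over the list alone, camera adjusted p = 0.099). Other large falls were in GstD7 (-6.34, adjusted p = 0.000132), Nplp4 (-6.28, adjusted p = 0.00303), CG11370 (-6.01, adjusted p = 0.00365), the cuticle gene Cpr47Ec (-5.59, adjusted p = 0.0038) and su(r), of pyrimidine breakdown (-5.22, adjusted p = 5.97e-05). The histone genes His2B:CG33872, His2B:CG33874 and His2B:CG33876 also passed. They are near-identical copies listed at 0 in both 16 h libraries, so no fold is given and their assignment is uncertain.

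In all, 4110 of 8332 genes passed at 16 h (49.3%), 1801 higher and 2309 lower, 2811 of them by at least 2-fold and 264 of them noncoding or mitochondrial. The share of higher calls was 43.8%, against 11.3% without scaling, 22.8% with rescaling over coding genes and 44% under quantile normalization. 2680 passed without fed replicate 2 and 3178 without both the 16 h library richest in ribosomal RNA and mutant replicate 2.

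Between 4 h and 16 h of starvation, 3 genes passed, all lower at 16 h. CG13135 stood at 20.9 and 27.7 at 4 h and at or under 0.09 in every other library (log2FC -4.60, SE 0.19, adjusted p = 0.00169). The aquaporin gene Prip went from 16.7 and 16.3 to 5.21 and 4.81 (-1.54, SE 0.11, adjusted p = 0.0234), and bdg went from 5.47 and 5.45 to 1.36 and 1.16 (-1.52, SE 0.11, adjusted p = 0.0234). These genes were named after their values were seen. At an unadjusted p under 0.05, 1337 genes differed, and the number that passed was 17 without 16 h replicate 1 and 24 without 16 h replicate 2 and was 1 without fed replicate 1, fed replicate 2, 4 h replicate 1, mutant replicate 1 or mutant replicate 2. Cpsf5 (-0.07, adjusted p = 0.918), Atg1 (-0.36, adjusted p = 0.482) and Atg8a (-0.21, adjusted p = 0.681) did not pass. The calls at 4 h and 16 h shared 1371 rises (380 for independent lists of the same sizes) and 1962 falls (615), with 4 genes in each opposite combination, and without scaling 464 rises were shared. Across genes, which are not independent replicates, the fold changes correlated at 0.913 (0.502 in simulations of unchanged groups that share the fed libraries) with a covariance of 2.062 (0.081 simulated). Both comparisons use the same fed libraries, which were not split between them.

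Genes of late larval life were far lower in the CPSF5 mutant than in wild type at 16 h. The labels give no age, stage or mutant strain background apart from the group. Stage or background thus cannot be told from an effect of the allele in any mutant comparison. Fbp1 stood at 2.87 ± 1.05 against 7369 ± 2445 (log2FC -10.88, SE 0.57, adjusted p = 0.000276), Lsp2 at 12.7 ± 5.70 against 24216 ± 691 (-10.86, SE 0.50, adjusted p = 0.000193) and Lsp1alpha at 9.45 ± 0.0491 against 12460.0 ± 413 (-10.22, SE 0.38, adjusted p = 0.000179). Fbp2 was lower too (-10.84, adjusted p = 0.000812). In means alone, with no test given, mutant Fbp1 also lay below fed (9.78 ± 4.55), as did Lsp2. The storage gene Lsp1gamma went the other way, with 132 and 204 in the mutant libraries against 0.067 ± 0.003 in wild type at 16 h (7.28, adjusted p = 0.00622), and 15.6 and 0.036 in the fed libraries. Of 6 storage genes 5 were lower and 1 higher (camera adjusted p = 0.000166, or adjusted p = 0.29 with an estimated correlation). Of 10 salivary gland markers, 7 were lower (camera adjusted p = 8.25e-06, or adjusted p = 0.233 with an estimated correlation). They included Sgs7 (-11.79, SE 1, adjusted p = 0.000995), Sgs5 (-10.81, adjusted p = 0.000911), Eig71Ee (-10.02, adjusted p = 0.000238) and Sgs8 (-9.55, adjusted p = 0.000586). The uncharacterised genes CG7606 (-9.65, adjusted p = 0.000379) and CG15404 (-9.58, adjusted p = 0.000458) were lower too. Of 13 ecdysone-response genes 7 were lower and none higher (9 adjusted over the list alone, camera adjusted p = 2.09e-05, or adjusted p = 0.233 with an estimated correlation), but 3 lower and 1 higher without scaling and 4 and 1 with rescaling over coding genes. The lower ones included br (0.64 ± 0.083; -3.53, SE 0.18, adjusted p = 0.000247), Eip74EF (-2.71, adjusted p = 0.000183) and EcR (-2.02, adjusted p = 0.00318). Of 10 fat body markers 6 were lower and 1 higher (camera adjusted p = 0.00148, or adjusted p = 0.428 with an estimated correlation), against 5 and 3 without scaling. The other list counts were the same adjusted over the list alone. The markers that are not storage genes went both ways, a set chosen after the values were seen: FASN1 was higher (753 and 221 in the mutant libraries; 1.79, adjusted p = 0.0472), Glut1 (-1.53, adjusted p = 0.0107) and CG2233 (-1.42, adjusted p = 0.00969) lower, and apolpp (0.27, adjusted p = 0.502), srp (-0.04, adjusted p = 0.905) and Lsd-1 (0.00, adjusted p = 1) did not pass.

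**Figure D3:**
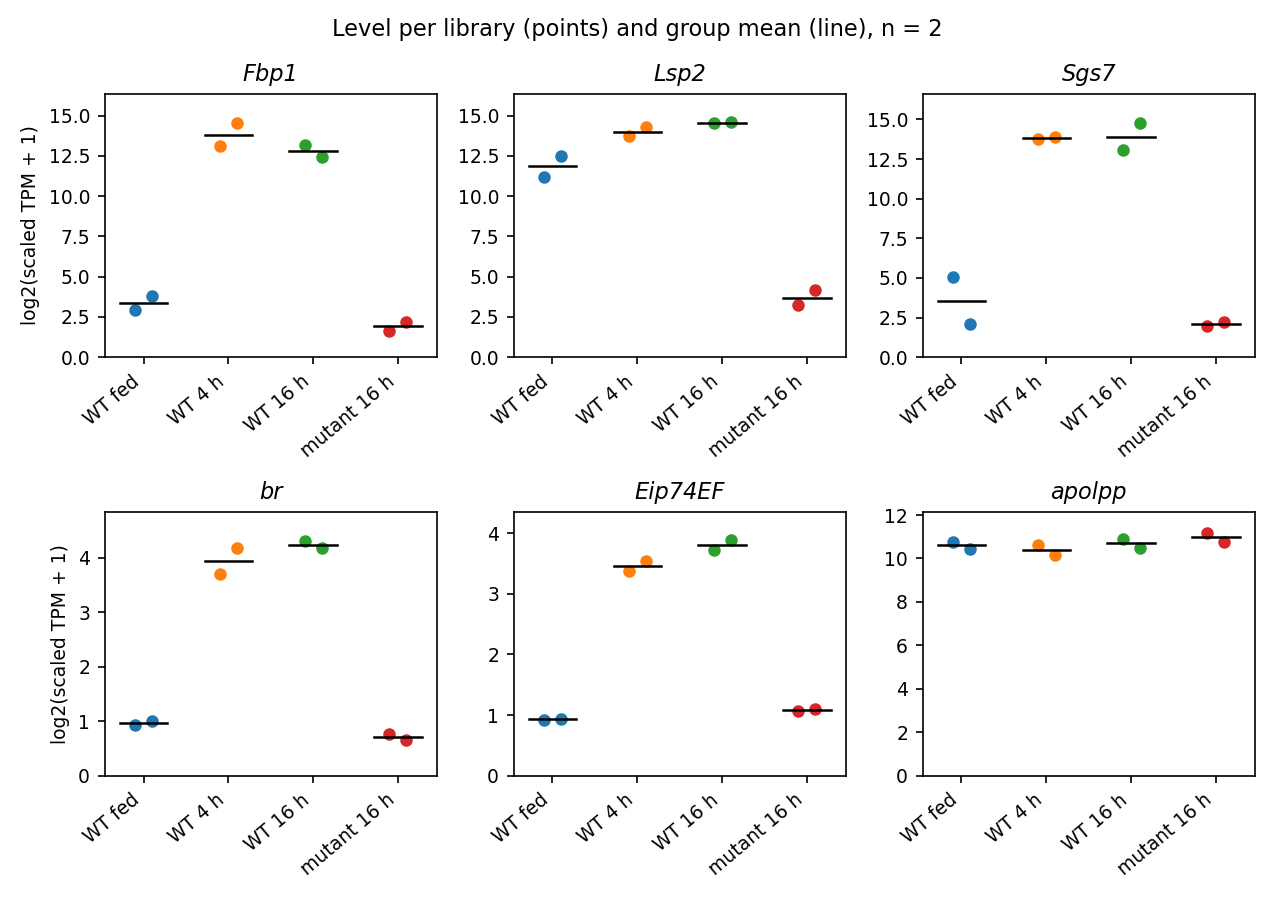
log2(scaled TPM + 1) (y axis) of the storage genes Fbp1 and Lsp2, the glue gene Sgs7, the ecdysone-response genes br and Eip74EF, and the lipoprotein gene apolpp in the 4 groups (x axis), where points are libraries and lines are means of n = 2. Both mutant libraries lie below both 16 h wild-type libraries for each gene but apolpp, whose log2FC of 0.27 did not pass.

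Many energy and lipid metabolism genes were higher in the mutant than in wild type at 16 h. Markers of other tissues were higher with them (10 of 12 for midgut, all 4 for trachea and oenocytes), and whether such tissue adds to the glycolysis, lipid, trehalose and glycogen genes was not tested. Cyt-c-p stood at 151 ± 11.6 against 21.9 ± 5.67 (log2FC 2.75, SE 0.23, adjusted p = 0.000993), with Cyt-c1 (2.79, adjusted p = 0.000738), ATPsynB (2.65, adjusted p = 0.00197) and ATPsynbeta (2.56, adjusted p = 0.00463) also higher. Of 72 oxidative phosphorylation genes 61 were higher and none lower (62 adjusted over the list alone, camera adjusted p = 1.67e-15, or adjusted p = 0.609 with an estimated correlation). Hex-C (3.53, adjusted p = 0.0024) and Eno (2.19, adjusted p = 0.00164) were among 12 of 14 glycolysis genes that were higher (the same adjusted over the list alone, camera adjusted p = 0.000138, or adjusted p = 0.233 with an estimated correlation). Men (4.49, SE 0.29, adjusted p = 0.000485), Gpdh1 (3.04, adjusted p = 0.00127), Baldspot (2.91, adjusted p = 0.00196) and Acsl (2.57, adjusted p = 0.00284) were among 11 of 19 synthesis genes (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000297, or adjusted p = 0.405 with an estimated correlation), and 17 were higher without scaling. Of these, 7 were higher without fed replicate 1, fed replicate 2, 16 h replicate 2 or mutant replicate 1 and 6 without 16 h replicate 1. Hmgs (2.53, adjusted p = 0.000456), Acadvl (2.19, adjusted p = 0.00156), yip2 (1.78, adjusted p = 0.0057) and CG3902 (1.74, adjusted p = 0.002) were among 14 rises and 2 falls in 24 lipolysis and oxidation genes (15 and 3 adjusted over the list alone, camera adjusted p = 0.0056, or adjusted p = 0.233 with an estimated correlation). The trehalose synthase Tps1 (2.95, adjusted p = 0.000541) and glycogen synthase Glys (2.15, adjusted p = 0.00264) were among 5 of 14 gluconeogenesis, trehalose and glycogen genes (6 adjusted over the list alone, camera adjusted p = 0.0215, or adjusted p = 0.445 with an estimated correlation), against 12 without scaling and 8 with rescaling over coding genes. Without 16 h replicate 2, 3 were higher. Without both 16 h replicate 1 (48.8% ribosomal RNA) and mutant replicate 2, 32 of 68 oxidative phosphorylation genes, 4 glycolysis, 8 synthesis and 3 lipolysis genes were higher.

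Higher calls were also found for many, but not all, ribosomal protein and ribosome biogenesis genes. Of 88 ribosomal protein genes 57 were higher and none lower (75 adjusted over the list alone, camera adjusted p = 8.6e-11, or adjusted p = 0.609 with an estimated correlation). Their median log2FC was 0.97, and RpL24-like (1.62, adjusted p = 0.00341), RpLP2 (1.59, adjusted p = 0.00567) and RpL34b (1.58, adjusted p = 0.00681) were among the largest. The count was 41 under quantile normalization and 85 without scaling. Leaving out 1 library gave 36 without either fed library, 10 without 16 h replicate 1, 18 without 16 h replicate 2, 20 without mutant replicate 1 and 10 without mutant replicate 2. Leaving out 16 h replicate 1 and mutant replicate 2 together left 0 of 87 (limma), with a median of 0.74. Of 29 ribosome biogenesis genes 19 were higher (21 adjusted over the list alone, camera adjusted p = 6.94e-06, or adjusted p = 0.609 with an estimated correlation). They included Non1 (1.68, adjusted p = 0.0024), Fib (1.5, adjusted p = 0.00734), nop5 (1.38, adjusted p = 0.00628) and hoip (1.31, adjusted p = 0.00579). At 14.2 ± 2.53, hoip stayed below its fed level of 249 ± 14.1. 12 were higher without either 16 h library and 1 without 16 h replicate 1 and mutant replicate 2. Of 17 aminoacyl-tRNA synthetases 9 were higher (the same adjusted over the list alone, camera adjusted p = 0.00549, or adjusted p = 0.609 with an estimated correlation), with HisRS (1.73, adjusted p = 0.00349) and ValRS (1.27, adjusted p = 0.00419). That count was 16 without scaling, 4 without 16 h replicate 1 or mutant replicate 2, 5 without mutant replicate 1 and 0 without both 16 h replicate 1 and mutant replicate 2 (limma).

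Digestive, immune and other genes with little or no signal in wild type at 16 h were among the largest rises. CG13461 stood at 678 ± 172 against 3.14 ± 0.184 (log2FC 7.34, SE 0.51, adjusted p = 0.000561), and the peptidase-like gene Nepl11 at 218 ± 73.7 against 0.429 ± 0.0329 (7.22, SE 0.49, adjusted p = 0.000541). Acbp6 (63.9 and 489 in mutant replicates 1 and 2), CG9682 (69.6 and 462), CG7290 (58.6 and 376), CG5550 (53.6 and 354) and mat (149 and 525) also passed and stood higher in replicate 2. Of 12 midgut markers 10 were higher (12 adjusted over the list alone, camera adjusted p = 0.000199, or adjusted p = 0.609 with an estimated correlation), including deltaTry (29.3 and 184; 5.56, adjusted p = 0.00477), LysX (4.88, adjusted p = 0.000784) and epsilonTry (6.22 and 41.9; 4.11, adjusted p = 0.00949). Midgut markers were higher in mutant replicate 2 than in replicate 1 by a median of 2.53 log2 units. Without replicate 2, 4 of 7 tested were higher, and without 16 h replicate 1, 5 of 13. Of 31 immune genes 5 were higher and 2 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.641), against 12 and 0 without scaling and 10 and 1 with rescaling over coding genes. Without mutant replicate 2, 4 were lower. The rises held TotC (931 and 360 against 5.34 and 2.44; 6.96, adjusted p = 0.00199), defensin (Def; 5.56, adjusted p = 0.00125), TotA (3622 ± 41.2 against 772 ± 154; 2.24, SE 0.23, adjusted p = 0.00179) and Listericin, at 30.2 and 91.3 in the mutant and listed at 0 in both 16 h wild-type libraries. BomS6, an immune peptide outside that list, was higher as well (7.21, adjusted p = 0.00161).

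Autophagy and insulin-pathway genes had no common direction in the mutant. Of 29 autophagy genes 6 were lower and 4 higher (the same adjusted over the list alone, camera adjusted p = 0.394), but 11 were higher and 2 lower without scaling, 7 and 4 with rescaling over coding genes, and 2 and 8 under quantile normalization. Atg7 (1.71 ± 0.26 against 14.8 ± 3.88; log2FC -2.53, SE 0.27, adjusted p = 0.00181) and Atg101 (-1.47, adjusted p = 0.0024) were lower and stayed so when any 1 library was left out. Higher calls numbered 1 without fed replicate 1, fed replicate 2 or 16 h replicate 1, 0 without 16 h replicate 2 (limma) and 2 without mutant replicate 1, where 3 were lower. Of 16 insulin and FOXO genes 3 were lower and 1 higher (the same adjusted over the list alone, camera adjusted p = 0.394), against 5 higher and 0 lower without scaling, 1 and 1 with rescaling over coding genes, and 1 and 5 under quantile normalization. The insulin receptor InR was higher (1.47, adjusted p = 0.00284). Thor, at 57.6 ± 33.0 against 203 ± 38.5, was lower (-1.91, SE 0.48, adjusted p = 0.0268), as was foxo (-0.96, adjusted p = 0.0148). Thor was not called without fed replicate 1 (adjusted p = 0.0545), fed replicate 2 (0.0541), 16 h replicate 1 (0.0645), 16 h replicate 2 (0.109) or mutant replicate 1 (0.103), and foxo not without 16 h replicate 1 (0.0636), mutant replicate 1 (0.0611) or mutant replicate 2 (0.0654). Without 16 h replicate 1, 16 h replicate 2 or mutant replicate 2, 1 gene of the list was lower, and without mutant replicate 1, 0 (limma). Of 18 cleavage and polyadenylation factors 4 were higher and none lower (2 adjusted over the list alone, camera adjusted p = 0.715; 7 higher without scaling), with su(f) (0.95, adjusted p = 0.00427) and Wdr33 (0.83, adjusted p = 0.00371). Leaving out any 1 fed, 16 h or mutant library left 2. The list median of 0.11 turned to -0.01 under quantile normalization, where 3 were higher and 1 lower.

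Of 12 fat body signals 3 were lower and 2 higher (the same adjusted over the list alone, camera adjusted p = 0.707), with Gbp1 lower (log2FC -1.93, adjusted p = 0.00781) and sun higher (2.89, adjusted p = 0.00235). The list's median was 0.04 and its mean -0.20. Without scaling 6 were higher and 2 lower, with rescaling over coding genes 3 and 2, and under quantile normalization 2 and 5. 1 was lower without mutant replicate 1. Among 24 cell cycle genes E2f2 alone passed, as lower (-0.46, adjusted p = 0.027; none passed in limma adjusted over the list alone), and it stood at 0.26 (adjusted p = 0.337) without scaling, where the median gene stood at 0.767. E2f2 was not called without any 1 fed, 16 h or mutant library (adjusted p from 0.0605 to 0.105). Among 20 heat shock genes Hsp60A alone passed, as higher (2.13, adjusted p = 0.00341; camera adjusted p = 0.394), but 10 were higher without scaling and 2 with rescaling over coding genes. Among 11 muscle markers bt alone was higher (0.67, adjusted p = 0.0109; camera adjusted p = 0.125), while 7 of 13 were without scaling and 3 of 13 under each of the other 2 scalings. bt was not called without 16 h replicate 2 (0.0542) or mutant replicate 1 (0.0505). Without either 4 h library 3 muscle markers were higher. For heat shock and muscle the count was 1 adjusted over the list alone.

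**Figure D4:**
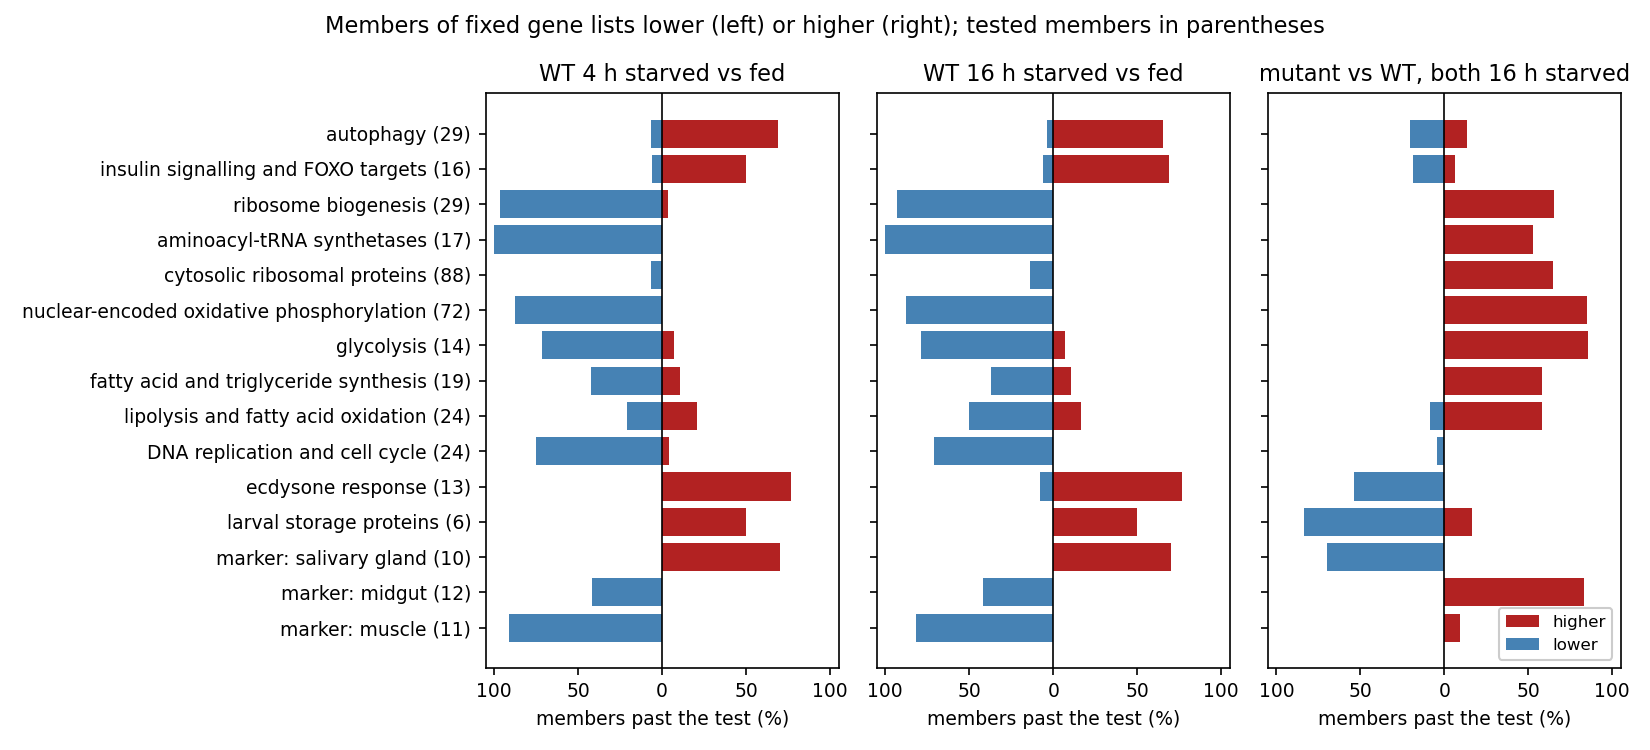
Percent of the tested members of 15 gene lists (number tested in parentheses) that were higher (right) or lower (left) past the test in 3 comparisons. Ribosome biogenesis fell in 28 of 29 members at 4 h and 27 at 16 h and was higher in 19 in the mutant, while without scaling the balance of the mutant bars turned to higher for autophagy (11 against 2), insulin signalling and FOXO targets (5 against 0) and DNA replication (1 against 0), and under quantile normalization the 16 h storage bar turned to lower (1 against 2).

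In all, 2791 of 8332 genes differed between mutant and wild type at 16 h (33.5%), 1781 higher and 1010 lower, 1829 of them by at least 2-fold and 223 of them noncoding or mitochondrial. The share of higher calls was 63.8%, against 92.1% without scaling, 83.4% with rescaling over coding genes and 54.8% under quantile normalization. The count was 1691 without 16 h replicate 2, 1714 without mutant replicate 1, 1653 without mutant replicate 2 and 839 without both 16 h replicate 1 and mutant replicate 2.

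Genes called at 4 h that also differed between mutant and wild type at 16 h mostly did so in the opposite direction. Of 1759 genes that rose at 4 h in wild type, 666 (37.9%) were lower in the mutant than in wild type at 16 h (213 for independent lists) and 100 higher (376), and of 2220 that fell, 906 (40.8%) were higher (475) and 57 lower (269). Without scaling, 233 were raised at 4 h and lower in the mutant, and 1968 lowered and higher. These comparisons share no library, and the fold changes correlated across genes at -0.494 (-0.004 simulated, with a covariance of -1.038 against -0.001). Wild type at 4 h and 16 h differed in only 3 called genes, so traits of starved wild type enter the comparisons with opposite signs. Simulations and independent lists leave this out, so a mutant state unrelated to starvation could give such counts and correlations too. For 16 h against fed, which shares the 16 h wild-type libraries, the counts were 713 (218) and 953 (494), with a correlation of -0.558 (-0.503 simulated; covariance -1.154 against -0.081), and with 1 wild-type 16 h library given to each comparison the correlation was -0.464 and -0.453. Against fed wild type, 3777 genes differed in the mutant (45.3%), 1914 higher and 1863 lower, 2401 without fed replicate 1 and 2129 without fed replicate 2. Of the genes that rose at 4 h, 814 (46.3%) were above fed in the mutant, and of those that fell, 1397 (62.9%) were below. Against fed, 17 of 29 autophagy genes were higher and 1 lower, 26 of 29 ribosome biogenesis genes lower and 1 higher, 16 of 17 synthetases lower, 2 of 72 oxidative phosphorylation genes higher and 3 lower, and 0 of 10 salivary gland markers passed (limma).

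Isoform use changed in 464 of 1948 genes at 4 h (798 isoforms), 502 at 16 h (864 isoforms) and 515 in the mutant against wild type at 16 h (878 isoforms), and in 0 genes between 4 h and 16 h (limma; 486 isoforms at an unadjusted p under 0.05). Adhr-RA went from 0% of the gene's TPM in fed larvae to 100% at 4 h and 16 h and to 0% in the mutant, with Adhr-RB in its place, EMC2A-RA from 0.271% to 100% at 4 h, and CG11089-RB from 6.18% to 97.7% at 4 h and 95.8% at 16 h. CG1943-RA went from 0% to 90% at 4 h and 90.4% at 16 h. In the mutant Eaat1-RA stood at 94% against 0% in wild type at 16 h, with Eaat1-RD at 0.93% against 97.6%, and ath-RA at 90.3% against 0%. Shares of 0% and 100% are estimates of the authors' tool, and transcripts that differ in a short stretch cannot be told apart well by short reads. Some of these genes were also low in unscaled TPM, with Adhr at 2.04 and ath at 2.09 in wild type at 16 h and EMC2A at 4.97 at 4 h. Their shares rest on little signal, unlike that of CG11089 (866 at 4 h). Of autophagy and cleavage and polyadenylation genes other than Cpsf5, the shares of Atg18a-RB (9.76% to 5.98%) and Atg4a-RB (3.48% to 1.4%) fell at 4 h. Their genes rose in unscaled TPM, Atg18a from 6.74 to 13 and Atg4a from 5.13 to 12.9. Both isoforms lay under the pseudocount of 1 in both groups, so these 2 calls follow the rise of the gene and not a fall of the isoform. In the mutant the shares of Pcf11-RB (12.4% in wild type, 5.74% in the mutant) and Pcf11-RD (12% and 5.2%) were lower and that of Pcf11-RC (51.6% and 71.3%) higher. Each of these calls was lost on leaving out single libraries. Atg18a-RB was lost without any 1 of the 8 (adjusted p from 0.0744 to 0.195), and Atg4a-RB without fed replicate 1 (0.0875), fed replicate 2 (0.0871) or 4 h replicate 2 (0.0639). Pcf11-RB was lost without 16 h replicate 1 (0.0593), mutant replicate 1 (0.08) or mutant replicate 2 (0.0671). Pcf11-RD was lost without any 1 of the 16 h or mutant libraries (0.0821 to 0.135), and Pcf11-RC without any 1 of the fed, 16 h or mutant libraries (0.0641 to 0.193). The count of genes at 4 h was 148 without fed replicate 1, 168 without fed replicate 2, 277 without 4 h replicate 2 and 295 without mutant replicate 2. At 16 h it was 181 without fed replicate 1, 212 without fed replicate 2, 231 without 16 h replicate 1 and 257 without 16 h replicate 2. In the mutant it was 201 without 16 h replicate 1, 162 without 16 h replicate 2, 156 without mutant replicate 1 and 106 without mutant replicate 2.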

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

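The tests of salivary gland tissue and of developmental stage in this part were chosen only after the result was seen. A difference between the 4 h and 16 h effects of starvation in wild type, tested as 16 h against 4 h, stood out for 3 genes. CG13135 differed by a log2FC of -4.60, Prip by -1.54 and bdg by -1.52. The number of genes that passed was 0 with only the 2 groups compared and 15 without scaling (limma). Prip and bdg lay above fed at 4 h, and bdg stood at 1.26 ± 0.141 at 16 h against 2.30 ± 0.0763 in fed larvae. Transcripts left out of the isoform tests also held a signal. The share of TPM on transcript identifiers without a match in the annotation was 2.36% and 1.63% at 4 h and 7.88% and 2.13% in wild type at 16 h, above the higher fed library (0.81%). Unmatched gene identifiers, with nearly the same share, stayed in the gene tests. The cause of this share was not tested.

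Glue and ecdysone-response genes, and 3 of 6 storage protein genes, were higher in wild type starved for 4 h than in fed. Salivary gland tissue in the dissections would raise glue genes but not storage proteins, whose 6 genes went apart at 4 h (median log2FC 1.46, quartiles -0.17 and 3.25), so this test does not tell. The gland genes ng1, ng2 and ng3 were taken to rise with such tissue, which assumes that glands of the stage sampled express them. They had a median of -1.96, but 0 of them passed (limma, adjusted p from 0.167 to 0.27), so this test does not tell either. A later developmental stage of the starved wild-type larvae would raise ecdysone-response genes, and 10 of 13 were higher, as a direct effect of starvation on these genes might do as well. The labels give no age or stage apart from the group, so stage, tissue and starvation stay unresolved here.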

How the results depend on the processing

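Of 274 named gene results, 11 were no longer called without scaling, 5 with rescaling over coding genes, 6 under quantile normalization, 1 with a pseudocount of 0.1, 8 with 5, 16 with no filter, 2 without the trend, 18 with only the 2 groups compared and 49 without 16 h replicate 1 and mutant replicate 2 (the 2 doubted libraries). The 11 include E2f2 in the mutant, at 0.26 without scaling, where the median of all genes was 0.767, so this change of sign comes from a shift common to all genes. A mean of 5 or more left 2470 calls at 4 h, 2543 at 16 h, 1832 in the mutant and 2140 for mutant against fed, with fewer genes tested. For 16 h against 4 h the calls numbered 15 without scaling, 1 with rescaling over coding genes, 13 under quantile normalization, 0 and 8 with pseudocounts of 0.1 and 5, 1 with no filter, 0 at a mean of 5 or more, 6 without the trend, 6 without the 2 doubted libraries and 0 with only the 2 groups compared (limma; 1337 at an unadjusted p under 0.05 in the main setting). In the mutant 4197 genes passed without scaling, 839 without the 2 doubted libraries and 1829 at 2-fold or more. Leaving out 1 library gave 2669 to 3926 calls at 4 h, 2680 to 4292 at 16 h, 1 to 24 for 16 h against 4 h, 1653 to 3057 in the mutant and 2129 to 4056 for mutant against fed. Genes with changed isoforms numbered 205, 230 and 328 (4 h, 16 h, mutant) with a pseudocount of 0.1, 739 and 856 (4 h, 16 h) with 5, 158, 182 and 206 at a gene mean of 20 or more, and 166 and 212 (4 h, 16 h) with the arcsine square root. Leaving out 1 library gave 148 to 368, 181 to 581 and 106 to 606. Lists past camera numbered 14, 16 and 14, with a range of 14 to 16, 15 to 18 and 14 to 16 on leaving out 1 library, and 0, 0 and 0 with an estimated correlation (camera in limma; 2, 2 and 5 at an unadjusted p under 0.05). Without scaling, 233 genes were raised at 4 h and lower in the mutant, 1968 lowered and higher, and 464 raised at both 4 h and 16 h. The correlation of mutant and 16 h effects was -0.453 with 16 h replicate 2 set against fed and replicate 1 against the mutant. Apart from smaller sets of genes or libraries, the cause was not tested. Accession order was used as a replicate block, a choice made after seeing the data. It gave 4063 calls at 4 h, 4257 at 16 h, 1 for 16 h against 4 h, 3001 in the mutant and 3906 for mutant against fed, 454, 507 and 527 genes with changed isoforms, and 14, 16 and 14 lists. Differences between the first and second library correlated at 0.277 to 0.342 among the wild-type groups but at -0.042, 0.141 and 0.039 between the mutant and fed, 4 h and 16 h, so the numbers were not taken to pair the samples. In all 4 groups the first library lay above the second on the third principal component and in genes above 0, so an unlabelled batch cannot be excluded. Depth is unknown, so how far counting noise limits low values cannot be told.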

Other observations

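The tests of digestive tissue in the 10 largest mutant rises and of scaling were chosen only after the result was seen, and the tests on ribosomal protein and respiration genes and on 3' UTRs were set before it. The genes in the next paragraphs were named after their values were seen. Some genes of the pathway of the nutrient-sensing kinase TOR changed in starved wild type. REPTOR-BP, whose product partners the transcription factor REPTOR that acts when TOR is low, went from 1.72 ± 0.268 in fed larvae to 34.3 ± 2.67 at 4 h (log2FC 3.70, SE 0.16, adjusted p = 3.93e-05) and 45.6 ± 1.84 at 16 h (4.10, SE 0.16, adjusted p = 5.97e-05), and the mutant stood at 56.3 ± 2.83. REPTOR rose at 4 h (1.15, adjusted p = 0.00312) and 16 h (2.34, adjusted p = 0.000229), and the amino acid transporter mnd fell at 4 h (-2.34, adjusted p = 0.000839) and 16 h (-2.31, adjusted p = 0.000861). In the 19 genes of the TOR list 4 rose and 1 fell at 4 h, with the same counts adjusted over the list alone (camera adjusted p = 0.287), but 2 rose and 3 fell without scaling and 4 and 3 with rescaling over coding genes. Without 4 h replicate 1, 3 fell, and without mutant replicate 1, 2. Some lysosomal genes rose at 4 h, among them the cathepsins CtsB (3.02, adjusted p = 0.000465) and cathD (3.05, adjusted p = 0.000847) and the cholesterol transporter Npc1a (2.09, adjusted p = 0.000436). Of 31 lysosome and V-ATPase genes 12 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0172, or adjusted p = 0.645 with an estimated correlation), although the median of 0.18 turned to -0.19 without scaling (6 rose, 2 fell) and -0.18 with rescaling over coding genes (6 and 5). Without fed replicate 1, 7 rose. Among translation factors 7 of 16 fell at 4 h, led by eIF6 (-3.57, adjusted p = 4.22e-05) and eIF2beta (-1.99, adjusted p = 0.000586), with the same count adjusted over the list alone. The list passed (camera adjusted p = 0.00762, or adjusted p = 0.531, not passed, with an estimated correlation). The count was 13 without scaling and 15 with rescaling over coding genes.

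Single genes of other classes changed by large amounts. The cytochrome P450 Cyp6g1 went from 1.14 ± 0.59 in fed larvae to 261 ± 99.3 at 4 h (log2FC 6.91, SE 0.34, adjusted p = 4.9e-05) and 177 ± 18.7 at 16 h (6.40, SE 0.34, adjusted p = 7.07e-05), and was lower in the mutant (39.3 ± 6.77, -2.15, SE 0.34, adjusted p = 0.00607). The collagen IV gene vkg fell from 195 ± 19.8 to 12.8 ± 8.74 at 4 h (-3.98, SE 0.47, adjusted p = 0.00102) and 12.5 ± 2.59 at 16 h (-3.86, SE 0.47, adjusted p = 0.0011), and stood at 192 ± 52.7 in the mutant (3.82, SE 0.47, adjusted p = 0.00279 against wild type at 16 h). The lipid transfer gene Apoltp fell at 4 h (-3.12, adjusted p = 0.000397) and was higher in the mutant (2.87, adjusted p = 0.00161). All 4 tested trachea and oenocyte markers were higher in the mutant, with the same count adjusted over the list alone (camera adjusted p = 0.012, or adjusted p = 0.609 with an estimated correlation), led by verm (2.97, adjusted p = 0.00199), and 2 were higher without mutant replicate 1. The male dosage compensation RNAs lncRNA:roX1 and lncRNA:roX2 stood at 119 and 165 in 4 h replicate 1 but at 0.143 and 0.442 in 4 h replicate 2, against 12.5 to 104 and 18.2 to 110 in the other 6 libraries. The 2 libraries of the 4 h group may therefore differ in sex, which the labels do not give, and the 4 h means, SDs and calls may carry such a difference.

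Among ribosomal protein, oxidative phosphorylation and digestive genes, many but not all were higher in the mutant than in wild type at 16 h. Gut tissue in the mutant dissections could raise digestive genes, and the 10 largest rises had a median log2 ratio of mutant replicate 2 over replicate 1 of 1.48, against 2.53 for the midgut markers that rose, which leaves this open. For 118 ribosomal protein and oxidative phosphorylation genes that rose, the excess over wild type was 0.97 times as large in replicate 2 as in replicate 1 (median). For the midgut markers that rose it was 6.58. The 118 genes were picked by passing the test, which favours genes whose replicates agree. Agreement between the replicates is thus partly built in, so the ratio cannot decide on gut tissue as a source of their rise. The other members of these lists are not covered. Oxidative phosphorylation genes were higher in 63 of 82 with rescaling over coding genes (76.8%, the lowest share), 58 of 70 under quantile normalization and 67 of 70 without scaling. The first and last of these counts carry a common upward shift, with the median gene at 0.437 and 0.767. Under quantile normalization the median gene stood at -0.015 and the list's median at 1.35, which speaks against scaling as the source of that part. Quantile normalization left 41 of 88 ribosomal protein genes higher (46.6%), against 85 of 88 without scaling and 82 of 92 with rescaling over coding genes, and none lower. Their median relative to the median gene was 0.643, 1.104 and 0.913 in that order. As the count rests on the scaling, scaling stays open there, and an effect of the genotype cannot be told from it.

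The loss of cleavage factor I has been described to shift polyadenylation toward proximal sites, so shorter 3' UTRs might be found in the mutant. Annotated 3' UTR length weighted by isoform share was tested in 971 genes. Between mutant and wild type at 16 h 99 passed, 36 of them shorter (36.4%) and 63 longer, so these lengths did not mostly shorten. Annotated length does not always follow the position of the 3' end, however. On the plus strand, Cpsf5-RB with 1375 nt ends at 9413637, before Cpsf5-RC with 423 nt at 9413835. The test therefore cannot decide on a shift toward proximal sites. Against fed wild type 94 passed, 28 shorter and 66 longer. Annotated isoforms may miss sites that reads would show, and single reads were not used here.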
